A study of Arabidopsis thaliana with 2 samples.

How the data were processed

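Genomic DNA from leaves of 1 Arabidopsis thaliana individual (ecotype Columbia, 45 days) was made into 2 MspJI libraries. Per the labels' protocols, 1.5 µg of DNA was digested for 16 h, fragments of about 28 to 35 bp were taken from a native gel, and the library was amplified for 6 cycles and sequenced on an Illumina HiSeq instrument. Both libraries form 1 group, and the replicate numbers come from the labels.

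For each library the authors deposited a table of tag counts, 1 row per CNNR cytosine with at least 1 tag, with the strand, the motif type and the context, per the deposited file description. The description calls the tables fractional methylation, but the values were whole numbers of 1 or more and were used as raw counts. A motif on both strands gives its tags to both cytosines: of the symmetric CG motifs, 99.97% in replicate 1 and 99.96% in replicate 2 were listed on both strands, with equal tags on both strands in 83.0% and 73.8%, so the tags of a pair are not independent. The genome build was TAIR9, per the submitters' processing notes. The aligner, its settings and any filter on repeated sequence are not given in the sources used here. Random placement of repeated reads or their removal would change the counts in repeated sequence.

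The bisulfite table was made by the authors from the alignments of another study of aerial tissues, per the deposited file description, and it is other plant material than the leaves profiled here. It gives for each CNNR cytosine a methylation level as a fraction, deposited by the authors, with read counts. The description lists 12 columns and the table has 14, so the meaning of the read columns was taken from their arithmetic: the fraction equals methylated reads over all C and T reads, within 0.001, in 98.3% of 18632371 rows. The deposited description also names an effective C and T count and reads of the opposite strand, and levels recomputed from the read counts alone were tried as an alternative. Methylated reads and coverage, both counts deposited by the authors, were used with the level, 5 further columns were not used, and 31 rows with an ambiguous context were left out. The table is 1 pooled sample, so its values carry no SD. Its median nuclear coverage was 3 reads, and 34.0% of nuclear cytosines had at least 5.

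A site was detected in a library with at least 1 tag. A cytosine was WGBS-methylated with coverage of at least 5, at least 2 methylated reads and a level of at least 0.2, and unmethylated with coverage of at least 5 and no methylated read. Since no genome was given, the CNNR cytosines listed in the WGBS table, 18528038 on chromosomes 1 to 5, stood for all CNNR cytosines. Positions that no bisulfite read covered are missing from this total, while overlap, context shares and counts of shared sites per named gene use all listed sites. Densities and the site counts given for single genes of the lists use only cytosines of the WGBS table, and the number of genes with a site uses all listed sites. MspJI cuts up to 16 bases from the modified cytosine, so a partner on the opposite strand gives a fragment of the selected length when it lies -2 to 5 bases away. Thinning drew tags of replicate 1 at random, without replacement, to the tag total of replicate 2. Level bins had edges of 0, 0.2, 0.4, 0.6, 0.8 and 1.

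Genes came from a RefSeq table of the assembly TAIR10.1, whose name differs from TAIR9. None of its coordinates are printed. It was used to place sites in nuclear genes on the assumption, from general knowledge, that both releases share the nuclear chromosome sequence. This was checked in part: the conserved base run of transfer RNA genes lay at 1 fixed offset from the annotated end in 469 of 625 such genes, only elsewhere in 7 and was not recovered in 149. The offset was chosen after seeing the data, and gene and feature values rest on this assumption. Organelle genes were not used, since this shared sequence is not assumed there. All 70 genes of the 4 lists were found by locus tag. The table has no strand, so the planned upstream window became a flank of 1 kb on either side of protein-coding genes, and it has no class of transposable elements. Each cytosine was placed in the first class that applied: protein-coding gene body, pseudogene, non-coding RNA gene, flank, intergenic.

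Genes were named by a rule fixed in advance: among nuclear protein-coding genes with at least 20 CNNR cytosines, the 10 with the most shared sites, the 10 with the most WGBS-methylated cytosines and no site in either library, the 5 with the most shared sites at a WGBS level of 0, and examples with many or few sites from the lists. MET1, some further list members, the most tagged sites and the chromosome bins were picked after their values were seen. Lists were set against 10000 random lists matched on deciles of CNNR number. Design, alternatives, named gene rule and lists were fixed before the data were examined.

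With 2 libraries of 1 individual there is no test between groups, and values are given per library with Wilson intervals of 95%, or as a mean ± SD. The libraries held 6375827 and 3392602 tags at a median of 1 per site, and whether this depth limits precision was not tested. Alternatives covered the minimum number of tags (2, 5 and 10), WGBS coverage (3 and 10), the methylation call, thinning, each library left out, scales, merged strands, windows, bin sizes and list statistics. The scripts were tested on simulated detection over 2918120 cytosines of chromosome 4, where shares were recovered within 0.575 percentage points, a list of doubled density lay at percentile 100, and 50 unchanged lists had a median percentile of 48.5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.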

Results

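DNA methylation was profiled in leaves of Arabidopsis thaliana, ecotype Columbia, grown for 45 days at 28 °C. The assay used MspJI, a restriction enzyme that recognises a modified cytosine followed, after any 2 bases, by A or G (the motif CNNR), and cuts beside it. When the motif is modified on both strands, the enzyme releases a short fragment with the modified cytosines near its centre, and fragments of about 28 to 35 bp were cut from a gel and sequenced. The 2 libraries formed 1 group, and per the series design both came from 1 individual, so their spread is technical and no test between groups applies. The design names 2 questions: how repeatable the profile was between these libraries, and how sensitive and specific it was against whole genome bisulfite sequencing (WGBS) of aerial tissues, which is other plant material. Replicate 1 held 6375827 tags at 988161 CNNR cytosines, and replicate 2 held 3392602 tags at 343162 cytosines. The median was 1 tag per listed cytosine in each library, and 61.1% of the sites in replicate 1 and 56.9% in replicate 2 rested on 1 tag. Intervals below are 95% Wilson intervals for counting error only, since reads without molecular identifiers are not independent molecules.

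The libraries shared more cytosines than chance placement would give, in all 3 contexts. On chromosomes 1 to 5, replicate 1 listed 969145 sites and replicate 2 listed 340672, of which 138480 were in both. These shared sites made up 40.6% (40.5 to 40.8) of replicate 2 and 14.3% (14.2 to 14.4) of replicate 1, 7.77 times the 17820 shared sites given by independent lists over the 18528038 nuclear CNNR cytosines of the WGBS table. Of replicate 2 sites, 50.6% (50.4 to 50.8) in CG, 36.9% (36.5 to 37.2) in CHG and 28.7% (28.5 to 29.0) in CHH were also in replicate 1 (H is A, C or T). Against independent lists within each context the order was the opposite, with 4.36 times the expected shared sites in CG, 5.79 in CHG and 7.59 in CHH. Sharing rose with depth at the site: 29.6% of replicate 2 sites with 1 tag were found in replicate 1, against 96.8% of the 1827 sites with 100 or more tags. With replicate 1 thinned to the tag total of replicate 2, the share of replicate 2 sites found fell to 30.4%.

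Tag numbers agreed between libraries over regions more than at single cytosines. Across the 138480 shared nuclear sites, Pearson's r of log2(tags + 1) was 0.487 and Spearman's rho was 0.289. Over the union of 1171337 sites, with 0 for a missing site, r was 0.00302 and rho was -0.366, values that are pulled down by construction, since most of these sites are at 0 in exactly 1 library and cytosines at 0 in both are left out. Tags summed in 100 kb bins gave r of 0.836 and rho of 0.765 over 1193 bins, and in 10 kb bins r was 0.660. These correlations are across sites or bins, which are not independent replicates. On a square root scale r at shared sites was 0.719, and without the top 1% of sites it was 0.358.

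CG cytosines were over-represented among detected sites in both libraries. They made up 46.6% (46.5 to 46.8) of nuclear sites in replicate 2 and 29.4% (29.3 to 29.5) in replicate 1, against 13.2% of all nuclear CNNR cytosines in the WGBS table. CHH made up 32.1% of sites in replicate 2 and 51.3% in replicate 1, against 70.9% of all CNNR cytosines. CHG shares were 21.2% and 19.3%, against 15.9%. The mean CG share was 38.0% ± 12.2 (SD, n = 2), and among sites found in both libraries CG made up 58.1%. By tags, CG held 64.6% of nuclear tags in replicate 2 and 50.4% in replicate 1. A single CG cytosine in a ribosomal RNA gene held 11.5% of nuclear tags in replicate 2 and 2.27% in replicate 1. Motifs on both strands also give their tags to both cytosines.

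Of the contexts, CG was the one in which MspJI recovered methylated cytosines best. Among nuclear CNNR cytosines covered by at least 5 bisulfite reads and called methylated (at least 2 methylated reads and a level of at least 0.2), replicate 1 detected 21.8% (21.7 to 21.9) of 340838 in CG, 12.3% (12.1 to 12.4) of 229989 in CHG and 3.89% (3.85 to 3.93) of 870766 in CHH. Replicate 2 detected 15.9% (15.8 to 16.0), 10.1% (9.93 to 10.2) and 2.35% (2.32 to 2.38). The means were 18.9% ± 4.16 in CG, 11.2% ± 1.57 in CHG and 3.12% ± 1.09 in CHH (SD, n = 2). The gap between CG and CHG exceeded the spread between libraries, as did the gap between CHG and CHH. Requiring 2 tags lowered sensitivity to 9.54%, 4.75% and 1.19%.

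Cytosines without any methylated bisulfite read were detected far more often by replicate 1 than by replicate 2. Replicate 1 detected 4.62% (4.56 to 4.67) of 558711 such CG cytosines, 4.35% (4.30 to 4.39) of 827858 in CHG and 3.42% (3.40 to 3.45) of 2982443 in CHH. The CHH share was close to the 3.89% that replicate 1 detected among WGBS-methylated CHH cytosines. Replicate 2 detected 0.314% (0.2998 to 0.3291), 0.316% (0.304 to 0.329) and 0.479% (0.471 to 0.487). The ratio of replicate 1 to replicate 2 was 14.7 in CG, 13.7 in CHG and 7.15 in CHH, and with replicate 1 thinned to equal tags it was 9.53, 8.94 and 4.67. Specificity, the undetected share of these cytosines, averaged 97.5% ± 3.04 in CG, 97.7% ± 2.85 in CHG and 98.0% ± 2.08 in CHH (SD, n = 2).

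A CG site listed by replicate 2 was nearly always methylated in the WGBS table, whereas a CHH site was called methylated less often. Of detected sites with at least 5 bisulfite reads, 95.4% (95.3 to 95.6) of 56822 CG sites, 82.9% (82.5 to 83.4) of 27883 CHG sites and 46.7% (46.2 to 47.1) of 43860 CHH sites of replicate 2 were WGBS-methylated. The shares in replicate 1 were 72.4% (72.1 to 72.7), 41.2% (40.9 to 41.6) and 22.2% (22.0 to 22.4). Of all covered nuclear cytosines, 36.4% in CG, 20.4% in CHG and 20.6% in CHH were WGBS-methylated. The CHH share of replicate 1 was thus near that of any covered CHH cytosine. The CHH share depends on the call: its mean was 34.4%, against 50.3% with 1 methylated read as the call and 21.3% with a level of at least 0.5. Sites found in both libraries gave 96.2% in CG, 85.1% in CHG and 47.5% in CHH. In replicate 1 the CG share rose from 66.8% of sites with 1 tag to 94.4% of the 1135 sites with 100 or more tags. In replicate 2 the same CG shares were 94.1% and 96.0%. In CHH the share rose from 21.4% to 41.5% in replicate 1. In replicate 2 it was 44.9% at 1 tag, 50.2% at 2 to 4 tags and 42.8% at 100 or more. The WGBS table itself called 13.8% of covered chloroplast CHH cytosines methylated, against 20.6% in the nucleus, while the chloroplast genome is taken as unmethylated in leaves.

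Detection rose with the WGBS level in CG and CHG and did not do so throughout in CHH. From a level of 0 to levels above 0.8, CG detection went from 0.314% to 17.2% in replicate 2 and from 4.62% to 23.1% in replicate 1. In CHG it went from 0.316% to 12.3% and from 4.35% to 14.3%. In CHH, replicate 2 detection was 0.479% at level 0, 2.75% (2.68 to 2.81) at levels of 0.2 to 0.4 and 1.76% (1.71 to 1.82) above 0.8. Replicate 1 went from 3.42% through 4.48% (4.40 to 4.56) to 3.12% (3.05 to 3.18) at the same levels. Spearman's rho between level and tags across covered cytosines averaged 0.285 ± 0.0336 in CG, 0.189 ± 0.0824 in CHG and 0.0460 ± 0.0482 in CHH (SD, n = 2).

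**Figure D1:**
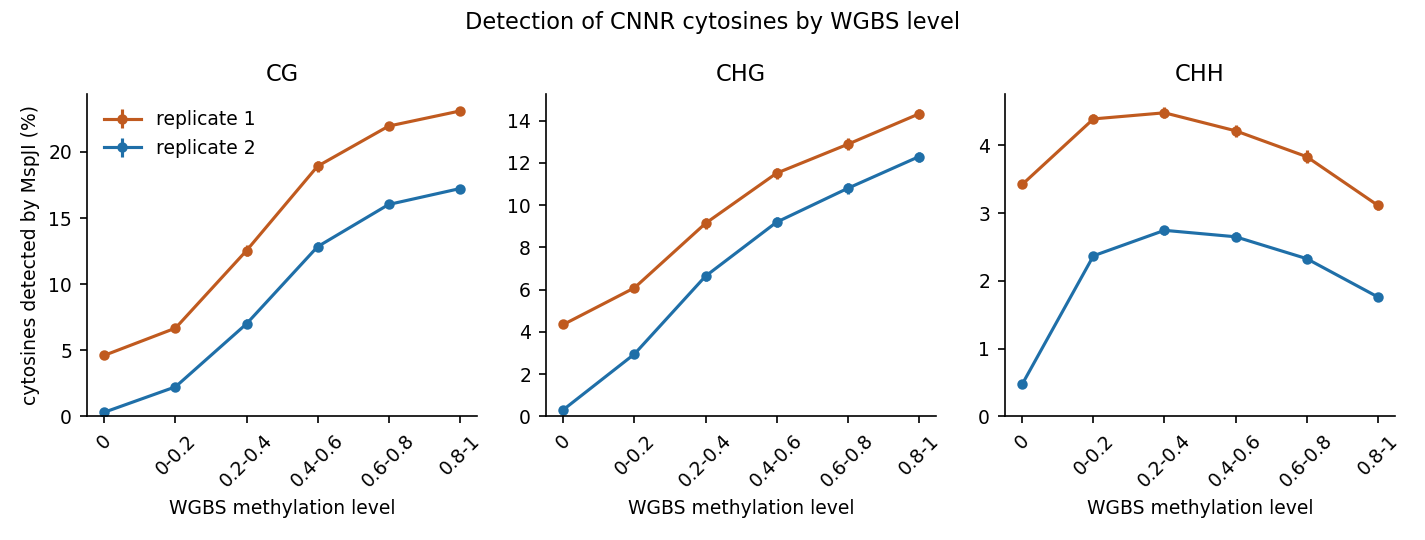
Share of nuclear CNNR cytosines detected by MspJI (y axis, percent) by WGBS methylation level (x axis, fraction) in CG, CHG and CHH. Points are single libraries with 95% Wilson intervals. Replicate 2 rises from 0.314% to 17.2% in CG, whereas in CHH it peaks at 2.75% and ends at 1.76%.

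Methylated cytosines were detected more often where the opposite strand also carried a methylated CNNR cytosine within the distance that gives a fragment of 28 to 35 bp. In CG, 28.0% (27.7 to 28.3) with such a partner were detected by replicate 1, against 13.4% (13.0 to 13.8) with covered partners of which none was called methylated. In replicate 2 the shares were 22.0% (21.7 to 22.3) and 7.10% (6.80 to 7.41). In CHG they were 16.3% and 8.60% in replicate 1, and 13.6% and 6.01% in replicate 2. In CHH they were 7.51% and 5.29%, and 6.39% and 2.82%. Methylated cytosines with no opposite-strand CNNR cytosine listed in that window were also detected, at 11.4% and 6.27% in CG, 7.33% and 5.61% in CHG and 2.74% and 1.27% in CHH in replicates 1 and 2. By its name, the motif type GnnC pairs cytosines at an offset of -3, outside that window. It held 52105 nuclear sites in replicate 1 and 25960 in replicate 2, so some of these cytosines may have had a partner there. The differences between those with a methylated partner and those with covered partners not called methylated averaged 14.7 ± 0.213 percentage points in CG, 7.66 ± 0.0873 in CHG and 2.90 ± 0.951 in CHH (SD, n = 2). At levels above 0.8 they were 12.4 ± 0.876, 5.53 ± 1.34 and 2.93 ± 0.687 points. With at least 10 bisulfite reads required, the differences were 8.17 points in CG, 8.42 in CHG and 0.742 in CHH. Requiring 2 tags gave 8.81 points in CG, 3.82 in CHG and 1.07 in CHH.

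Chloroplast DNA, the unmethylated control of this design, gave many tags in replicate 1 and hardly any in replicate 2. Replicate 1 held 761088 chloroplast tags, 11.9% (11.91 to 11.96) of its total, at 13586 cytosines. Replicate 2 held 615 chloroplast tags, 0.0181% (0.0168 to 0.0196), at 464 cytosines. Mitochondrial tags were 0.395% of replicate 1 and 0.128% of replicate 2. The mean chloroplast share of 5.98% ± 8.43 (SD, n = 2) therefore describes neither library.

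With at least 1 tag, annotated pseudogenes carried the densest MspJI sites of the 5 classes, and protein-coding gene bodies were denser in CG than in CHG or CHH. In CG, replicate 1 detected 173 (172 to 175) and replicate 2 170 (169 to 172) sites per 1000 CNNR cytosines in pseudogenes, and 97.0 (96.6 to 97.5) and 37.6 (37.3 to 37.9) in protein-coding gene bodies. The pseudogene class holds 4843 genes, and the annotation used here has no separate class for transposable elements. In CHG the pseudogene values were 116 and 103 per 1000, against 44.2 and 4.40 in protein-coding gene bodies, which is a ratio of 2.62 in replicate 1 and 23.4 in replicate 2. In CHH the ratios were 1.35 and 18.0. In replicate 1, gene bodies held 44.2 CHG and 30.5 CHH sites per 1000, near or below its background. Of cytosines without a methylated bisulfite read, that library detected 4.35% in CHG and 3.42% in CHH. The replicate 1 comparisons with gene bodies in CHG and CHH thus start from that background. Within 1 kb of protein-coding genes, CG sites numbered 76.4 and 31.2 per 1000, so gene bodies were 1.27 and 1.21 times as dense as their flanks, whereas CHG and CHH sites were denser in these flanks than in the bodies. Intergenic sequence lay between the gene bodies and the pseudogenes, with 135 and 102 CG sites per 1000. The authors' WGBS table gave mean CG levels of 0.767 in pseudogenes, 0.574 in intergenic sequence, 0.231 in the flanks and 0.192 in protein-coding gene bodies. Means of the libraries in CG were 172 ± 2.29 per 1000 in pseudogenes, 119 ± 22.7 in intergenic sequence and 67.3 ± 42.0 in protein-coding gene bodies (SD, n = 2). Requiring 2 tags lowered the pseudogene mean to 83.2 and the intergenic mean to 62.1 per 1000. At 10 tags 2 orders turned: intergenic sequence (13.995 CG sites per 1000) passed pseudogenes (12.6), and flanks (4.61) passed gene bodies (4.22), as means of the libraries.

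**Figure D2:**
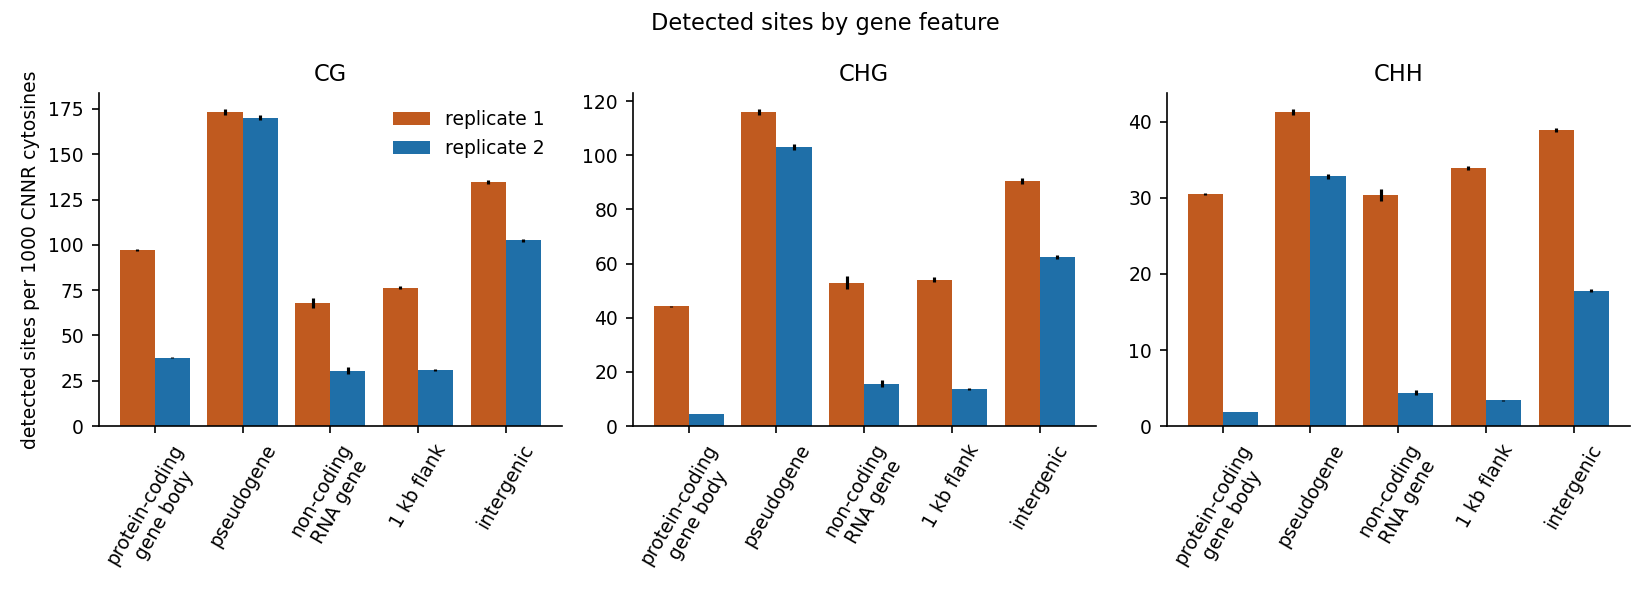
Detected sites per 1000 CNNR cytosines (y axis) in 5 feature classes (x axis) for CG, CHG and CHH, with bars for each library and 95% Wilson intervals. The libraries nearly coincide in pseudogenes in CG (173 and 170) and part in protein-coding gene bodies (97.0 and 37.6).

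The densest bin of each chromosome had a WGBS CG level of 0.711 to 0.852, but some bins were almost empty at similar levels. The densest 100 kb bin of chromosome 1, from 14500001 to 14600000 (TAIR9), held 130 sites per 1000 CNNR cytosines in replicate 1 and 152 in replicate 2, against chromosome medians of 41.9 and 6.75. On chromosome 3 the peaks lay at 13500001 to 13600000 in replicate 1, with 104 per 1000, and at 13600001 to 13700000 in replicate 2, with 114. On chromosome 4 both libraries peaked at 3000001 to 3100000, with 106 and 109 per 1000, and on chromosome 5 both peaked at 11700001 to 11800000, with 126 and 124. On chromosome 2, replicate 1 peaked at 3600001 to 3700000, with 111 per 1000, and replicate 2 at 5300001 to 5400000, with 93.2. Over 1193 bins, site density and WGBS CG level had a Spearman's rho of 0.758 in replicate 1 and 0.903 in replicate 2, a mean of 0.830 ± 0.103 (SD, n = 2). On chromosome 1 alone rho was 0.584 in replicate 1 and 0.847 in replicate 2. There the bin from 15300001 to 15400000 held 0.417 and 0.536 sites per 1000 at a CG level of 0.853, and the bin from 14800001 to 14900000 held 9.27 and 2.85 at 0.854. Whether tags could be placed in these bins was not tested. The density of the libraries correlated with rho of 0.827. Bins are neighbours on a chromosome and not independent replicates.

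**Figure D3:**
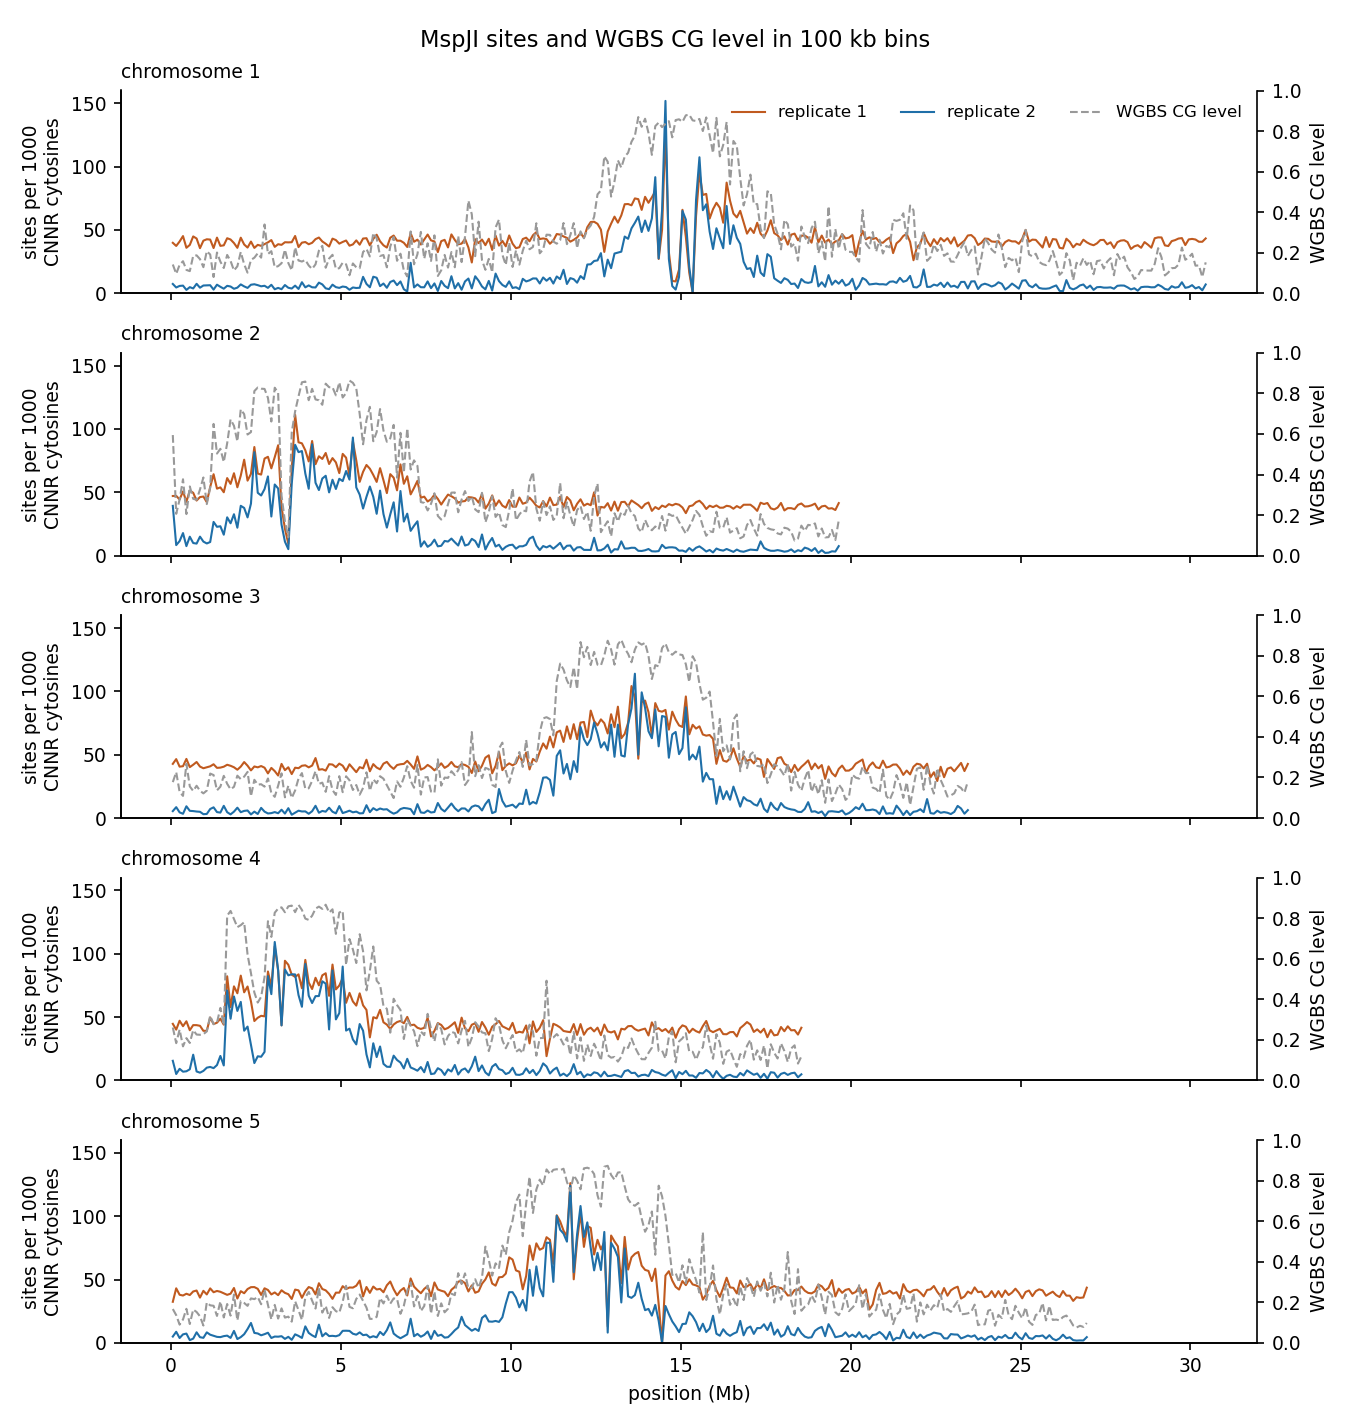
Detected sites per 1000 CNNR cytosines in 100 kb bins (left axis, solid lines, 1 per library) and mean WGBS CG level (right axis, fraction, dashed grey) along chromosomes 1 to 5 (x axis, Mb). The median bin holds 42.2 sites per 1000 in replicate 1 and 7.30 in replicate 2. Both lines peak where the WGBS level is high, with gaps such as 0.417 and 0.536 per 1000 on chromosome 1 where that level stays high.

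Of 27371 protein-coding genes with at least 20 CNNR cytosines, 26740 (97.7%) held a site in replicate 1 and 12060 (44.1%) in replicate 2. Replicate 1 also detected 3.42% to 4.62% of cytosines without a methylated bisulfite read, so a site there does not mark a gene as methylated. A shared site was found in 8838 genes (32.3%), and 2709 genes held at least 5. Across 21986 genes with at least 10 covered CG cytosines, the WGBS-methylated CG share and the detected CG share had a Spearman's rho of 0.644 in replicate 1 and 0.724 in replicate 2. Genes are not independent replicates in these correlations.

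Of the 10 genes with the most shared sites, 5 had WGBS coverage far above that of the nucleus. AT2G08986 led with 307 shared sites between positions 3618830 and 3626175 of chromosome 2, followed by AT1G40104 with 275 (15081954 to 15085893 of chromosome 1) and AT2G07981 with 129 (3615229 to 3617676 of chromosome 2). Median WGBS coverage of their CNNR cytosines was 78, 97 and 72 reads, against 3 over the nucleus. AT2G01008, with 80 shared sites near the start of chromosome 2, and AT3G41762, with 62 on chromosome 3, had median coverage of 789.5 and 991.5. MEE38 (AT3G43160), with a median coverage of 6, held 117 shared sites between 15166578 and 15168217 of chromosome 3, with 42.1 and 41.6 detected sites per 100 CNNR cytosines in replicates 1 and 2. AT1G58602 (21747200 to 21759395 of chromosome 1) held 63 shared sites and AT5G39770 (15919369 to 15927289 of chromosome 5) held 51. AT3G22125 and AT3G22142 both had 52, over the same positions 7803966 to 7807368 of chromosome 3, and cannot be counted as separate genes here.

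Some genes that the WGBS table called methylated had no MspJI site in either library. Replicate 1 detected 3.42% or more even of cytosines without a methylated bisulfite read, so these genes lay below that background too. If that background is even over the genome, a lack of cutting at methylated cytosines would not by itself account for this. Whether tags could be placed in these genes was not tested. AT3G60950 on chromosome 3 had 335 methylated of 483 covered CNNR cytosines and no site. On chromosome 1, AT1G24909 had 168 of 233, AT1G24807 had 144 of 190, AT1G25155 had 137 of 194, AT1G25083 had 121 of 163 and AT1G25180 had 67 of 93. AT1G25141 with 62 of 71, AT1G25112 with 53 of 57, AT2G07687 with 52 of 196 and the germin-like gene GER2 (AT5G39190) with 51 of 180 completed the list. In total 599 of the 27371 genes had no site in either library. Shared sites whose WGBS level was 0 at coverage of at least 5 numbered 13 in AT2G08986, 9 in AT2G07981, 8 in AT4G05612, 7 in MEE38 and 5 in TOR (AT1G50030), which encodes the target of rapamycin kinase.

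By their medians over all CNNR cytosines with at least 1 tag, the 4 gene lists lay at or below genes matched on the number of CNNR cytosines. This did not hold for housekeeping genes by CG sites (percentile 59.5) or for imprinted genes at 2 tags (57.9), as means of the libraries. All 19 genes of the DNA methylation machinery held a site in replicate 1, 15 held one in replicate 2 and 13 held a shared one. Their median density was 4.47 sites per 100 CNNR cytosines in replicate 1 and 0.577 in replicate 2, at the 32.2 and 10.4 percentiles of 10000 random lists, whose medians were 4.61 and 0.827. NRPD1 (AT1G63020), the largest subunit of RNA polymerase IV, had the highest replicate 2 density of this list, with 48 sites among 1429 CNNR cytosines and 25 of them shared. DCL3 (AT3G43920), which makes small RNAs that direct methylation, had 34 sites and RDR2 (AT4G11130), an RNA-dependent RNA polymerase, had 17. The chromomethylase CMT3 (AT1G69770), DRM1 (AT5G15380), the chromatin remodeller DDM1 (AT5G66750) and DML3 (AT4G34060) had no site in replicate 2, while replicate 1 listed 32, 18, 17 and 19 there. These were 3.37, 2.99, 2.31 and 2.41 per 100 CNNR cytosines, below the 3.42% of unmethylated CHH cytosines that replicate 1 detected. MET1 (AT5G49160), which maintains CG methylation, had 55 sites in replicate 1, 10 in replicate 2 and 5 shared.

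Of the 17 genes in the list of imprinted and epiallelic genes, all held a site in replicate 1, 6 held one in replicate 2 and 3 held a shared site. Their list median lay at the 30.0 and 16.8 percentiles in replicates 1 and 2, and the mean at 5.87 and 0.12. Requiring 2 tags moved the median from the 23.4 to the 57.9 percentile, as a mean of the libraries. FWA (AT4G25530), a homeodomain gene silenced in vegetative tissue, had 24 sites in replicate 1, 5 in replicate 2 and 2 shared ones at adjacent positions. HDG9 (AT5G17320) had 4 sites in replicate 2, all shared, and PAI3 (AT1G29410) had 2, both shared and at adjacent positions. PAI2 (AT5G05590) and EPF2 (AT1G34245) had 1 site each in replicate 1 and none in replicate 2.

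Of 20 photosynthesis genes, which leaves express strongly, 19 held a site in replicate 1, 7 in replicate 2 and 2 a shared one, with list medians at the 16.4 and 46.1 percentiles and means at 2.24 and 31.1. The list and random medians were both 0 in replicate 2. LHCA1 (AT3G54890), a light-harvesting protein of photosystem I, had 13 and 6 sites, 4 of them shared. CAB1 (AT1G29930) held 2 shared sites, at adjacent positions and both without a methylated bisulfite read. PETE1 (AT1G76100), a plastocyanin gene, had no site in either library among 193 CNNR cytosines. Housekeeping genes were at the 29.3 and 20.2 percentiles by median, and by mean at 43.5 and 88.0. By CG sites alone their median lay at the 59.5 percentile, as a mean of the libraries. Of these 14 genes, 7 held a site in replicate 2, 1 of them (ROC3, AT2G16600) outside the WGBS table, led by the ubiquitin-conjugating enzyme gene UBC21 (AT5G25760) with 16 sites and the actin gene ACT8 (AT1G49240) with 16, of which 8 and 12 were shared. UBQ10 (AT4G05320) and ACT2 (AT3G18780) had none in replicate 2. With 2 libraries of 1 group these percentiles describe the libraries and test nothing, and the median in replicate 2 was 0 for 3 of the 4 lists.

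**Figure D4:**
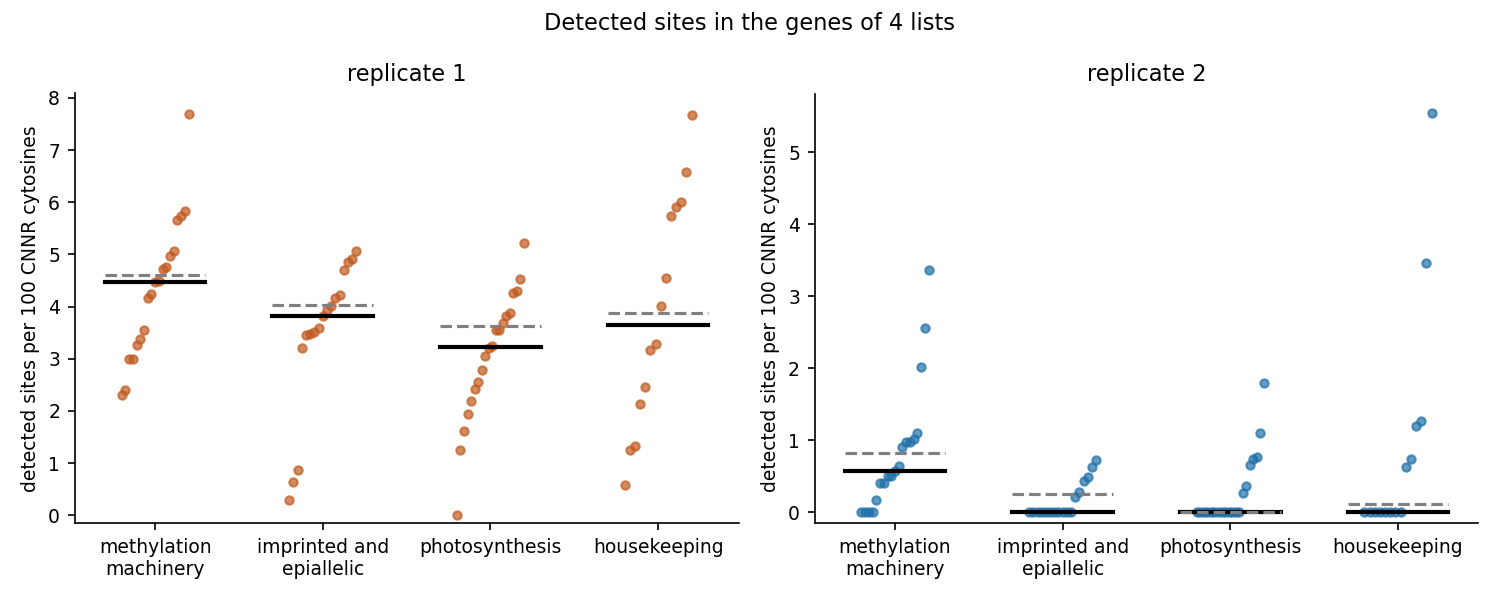
Detected sites per 100 CNNR cytosines (y axis) for each gene of 4 lists (x axis), 1 panel per library. Points are genes, black lines list medians and dashed grey lines the median of matched random lists. NRPD1, UBC21 and ACT8 stand highest among the listed genes in replicate 2.

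Tags were concentrated on few cytosines, led by 1 in a ribosomal RNA gene. The top 1% of nuclear sites held 56.1% of nuclear tags in replicate 1 and 71.2% in replicate 2, a mean of 63.7% ± 10.7 (SD, n = 2). The CG cytosine at position 14198165 on the plus strand of chromosome 3 was first in both libraries, with 126640 tags in replicate 1 and 389348 in replicate 2, which is 2.27% and 11.5% of nuclear tags. It lay in the ribosomal RNA gene AT3G41768, and WGBS coverage there was 1692 reads. The CG cytosine at position 14202342 of the same chromosome was the third in both libraries, with 56192 and 51205 tags and 1639 bisulfite reads. In CHG, position 4005969 of chromosome 4 was the second in replicate 1, with 57668 tags against 7884 in replicate 2. Position 11703560 of chromosome 5 was the second in replicate 2, with 55440 tags against 31142 in replicate 1.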

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

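The tests of depth, of unmethylated double motifs, of unselected fragments and of amplification were chosen only after the result was seen; those of unconverted reads, missing partners and collapsed repeats were not. Some wording and bounds also changed after values were seen. The test of unselected fragments first asked only for shares under 1.5 times apart, which the data met; a ratio of organelle tags within 3 times that of bisulfite reads was added later, and was not met. The bound for double motifs first asked for a ratio of at least 2 with a lower limit above 1.5, which the data met, and was then raised to a lower limit above 2, which leaves the test undecided. The CHH pattern was first stated as detection that does not rise with the WGBS level, and was restated because detection rises from level 0 before it falls; the predictions of its tests were kept.

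Sites were listed at cytosines that the comparison with WGBS does not reach. In replicate 1, 9.77% of sites, and in replicate 2, 7.62%, lay at cytosines absent from the bisulfite table. Among cytosines in both tables, the stated context differed for 0.315% of sites in replicate 1 and 0.625% in replicate 2.

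Replicate 1 held far more chloroplast tags and detected far more unmethylated cytosines than replicate 2. Depth alone is argued against, since with equal tags replicate 1 still detected 9.53 times the share of WGBS-unmethylated CG cytosines. Unselected DNA fragments spread over all genomes stay open: replicate 1 detected unmethylated CG, CHG and CHH at shares at most 1.35 times apart (1.52 in replicate 2), as an even spread would, but it held 30.2 chloroplast tags per mitochondrial tag against 2.77 among bisulfite reads, and the organelle DNA content of these leaves is not known. Cutting at unmethylated double motifs cannot be told apart from double counting. In the chloroplast of replicate 1, cytosines of the symmetric CG motif held 2.45 times the mean tags of all other CG cytosines (bootstrap interval 1.73 to 3.48). Those others can lie in other double motifs, which were not set apart, and giving tags to both cytosines can alone produce up to 2. The design holds 1 group, so no biological explanation was tested.

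CHH detection was no higher at WGBS levels above 0.8 than at 0.2 to 0.4. Missing partners may account for part of this: with a methylated opposite-strand partner, replicate 2 detection was 1.06 percentage points higher above 0.8 (7.11%, 6.68 to 7.56) than at 0.2 to 0.4 (6.05%, 5.73 to 6.38). Detection was not confined to cytosines with a listed partner: replicate 2 detected 1.27% of methylated CHH with none listed against 0.479% of unmethylated CHH. These shares do not show release without a partner. Cytosines without bisulfite reads are not listed, partners at an offset of -3 lie outside the window, and cytosines near a methylated CG or CHG were not set apart. WGBS-methylated CHH cytosines with covered but no methylated CG or CHG within 50 bp were used to test for unconverted bisulfite reads. Replicate 2 detected them at 0.467 times the share of unmethylated ones, so unconverted reads may underlie these calls (13.6% of all). Such calls were no more numerous above 0.8 (32549, of 256764 covered CHH) than at 0.2 to 0.4 (35751, of 259272). These counts cannot decide whether such calls underlie the lower detection above 0.8. Methylated CHH cytosines with no covered CG or CHG within 50 bp (200425, 23.0% of all) could not be classed and are left out. Near a methylated CG or CHG detection still went from 3.55% to 2.70%. No biological explanation was tested, and the bisulfite table comes from other plants.

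A small share of cytosines held a large share of nuclear tags: the top 0.1% of sites held 40.9% in replicate 1 and 57.8% in replicate 2. Amplification of single molecules in 1 library is argued against, since 84.1% of the top 0.1% of sites in replicate 2 were also in the top 0.1% of replicate 1. Repeated sequence collapsed onto 1 copy of the assembly is a candidate explanation: median WGBS coverage of these top sites was 17.25 times that of all detected sites in replicate 1 and 39.25 times in replicate 2. No biological explanation was tested.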

How the results depend on the processing

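The partner window of -3 to 5, levels from read counts alone, and CHH calls restricted to those near a methylated CG or CHG were added after seeing the data, as were the per-library values of specificity. No paired analysis was possible because the 2 libraries form 1 group and no result comes from a test. The 38 values were recomputed under 283 alternatives, and every alternative set in advance was run, with the upstream window replaced by flanks. A value counted as moved beyond 1 SD between libraries, beyond the 95% interval for overlap shares and correlations, or by over 1.5 times for counts of sites. By these limits 100 alternatives moved a value and 121 did not; thinning, for example, left 647661 sites in replicate 1 and 103701 shared sites, within 1.5 times. Under these alternatives no correlation or partner difference changed sign, but some orders turned. As means of the libraries, imprinted genes went above matched lists at 2 tags, and housekeeping genes did so by CG sites and by the mean. By the mean, housekeeping genes lay above only in replicate 2 (percentile 88.0, against 43.5 in replicate 1). At 10 tags gene bodies fell below flanks, and pseudogenes below intergenic sequence, in CG density. At 2 tags the mean CG share of sites (45.3%) passed that of CHH (35.5%). With WGBS coverage of at least 10, the CHG partner difference (8.42 points) passed that in CG (8.17). The remaining 62 leave out 1 library and cannot move by more than 1 SD by construction, so they show no stability. A higher tag minimum lowers site counts, sensitivity and densities by construction, and for all other moves the cause was not tested. The median site has 1 tag, and whether depth limits the rest was not tested.

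With at least 2, 5 and 10 tags, nuclear sites numbered 371660, 118043 and 52661 in replicate 1 and 147186, 50296 and 21329 in replicate 2, of which 52498, 15319 and 7369 were shared. These were 35.7%, 30.5% and 34.5% of replicate 2 and 14.1%, 13.0% and 13.99% of replicate 1. Pearson's r became 0.552, 0.619 and 0.658, and Spearman's rho 0.329, 0.424 and 0.470. Sensitivity in CG became 9.54%, 3.50% and 1.73%, in CHG 4.75%, 1.68% and 0.837%, and in CHH 1.19%, 0.430% and 0.221%. Spearman's rank correlation between level and tags became 0.212, 0.130 and 0.0908 in CG, and at 5 and 10 tags 0.0824 and 0.0605 in CHG. The partner difference became 8.81, 3.33 and 1.62 points in CG, 3.82, 1.47 and 0.837 in CHG, and 1.07, 0.352 and 0.182 in CHH. The CG share of sites was 51.2% at 10 tags, and the CHG share 18.35% at 5 tags and 18.25% at 10. CG sites per 1000 became 83.2, 28.4 and 12.6 in pseudogenes, 21.5, 7.24 and 3.77 in non-coding RNA genes, and 62.1, 25.9 and 13.995 in intergenic sequence. At 5 and 10 tags they were 9.77 and 4.22 in protein-coding gene bodies and 9.03 and 4.61 in flanks. Mean list percentiles at 2 tags were 57.9 for imprinted and 40.2 for housekeeping genes, and at 5 tags 39.6 for the methylation machinery and 39.5 for imprinted genes.

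With replicate 1 thinned, shared sites were 30.4% of replicate 2 and 16.0% of replicate 1, r was 0.49995 and CHG sensitivity 9.27%. With strand pairs merged the shares were 38.4% and 12.4%. Pearson's r was 0.472 with a pseudocount of 0.5, 0.719 on a square root scale and 0.358 without the top 1% of sites, where rho was 0.268. Sites in both libraries gave sensitivity of 8.33% in CG, 3.90% in CHG and 0.786% in CHH, and sites in either gave 29.4%, 18.4% and 5.45%. WGBS coverage of at least 10 gave CHH sensitivity of 4.79% and partner differences of 8.17, 8.42 and 0.742 points in CG, CHG and CHH, and coverage of at least 3 gave 6.72 in CHG. A level of at least 0.5 gave 13.3 points in CG and 5.20 in CHG, 1 methylated read 15.1 and 8.65, the symmetric partner alone 22.3 and 10.4, and the window of -3 to 5 gave 15.1 and 7.88. The methylated share of detected CHH sites was 50.3% with 1 methylated read and 21.3% at a level of at least 0.5. Flanks of 2 kb gave 141 CG sites per 1000 in intergenic sequence. By the mean, lists lay at percentiles 2.995 for imprinted and 65.7 for housekeeping genes, and by CG sites at 13.7 and 59.5. The top 0.1% of sites held 49.3% of tags and the top 10% held 80.1%.

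Single libraries ranged as follows. The share of sites was 29.4% to 46.6% in CG, 19.3% to 21.2% in CHG and 32.1% to 51.3% in CHH. Sensitivity was 15.9% to 21.8%, 10.1% to 12.3% and 2.35% to 3.89%, specificity 95.4% to 99.7%, 95.7% to 99.7% and 96.6% to 99.5%, and the methylated share of detected sites 72.4% to 95.4%, 41.2% to 82.9% and 22.2% to 46.7%. Spearman's rank correlation of tags with level was 0.262 to 0.309, 0.131 to 0.247 and 0.0119 to 0.0801, and the partner difference 14.6 to 14.9, 7.60 to 7.72 and 2.23 to 3.57 points. Tags were 0.0181% to 11.9% chloroplast and 0.128% to 0.395% mitochondrial. CG sites per 1000 were 37.6 to 97.0 in protein-coding gene bodies, 170 to 173 in pseudogenes, 30.7 to 67.9 in non-coding RNA genes, 31.2 to 76.4 in flanks and 102 to 135 in intergenic sequence. Spearman's rank correlation across bins was 0.758 to 0.903. Percentiles were 10.4 to 32.2 for the methylation machinery, 16.8 to 30.0 for imprinted, 16.4 to 46.1 for photosynthesis and 20.2 to 29.3 for housekeeping genes. The top 1% of sites held 56.1% to 71.2% of tags.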

Other observations

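The bins were chosen after their values were seen. Some bins were nearly empty in both libraries although the covered CG cytosines were methylated. On chromosome 5, the bin from 14400001 to 14500000 held 0.0958 sites per 1000 of its 10437 CNNR cytosines in replicate 1 and 0 in replicate 2, with a WGBS CG level of 0.723 over 171 covered CG cytosines. On chromosome 1, the bin from 15300001 to 15400000 held 0.417 and 0.536 sites per 1000, with a CG level of 0.853 over 240 covered CG cytosines. In replicate 1 both bins lay below its 3.42% detection of unmethylated CHH cytosines. An absence of placed tags therefore cannot be told apart from a lack of cutting. A bin on chromosome 2, from 3400001 to 3500000, differed, with a CG level of only 0.0900 over 3978 covered CG cytosines. It held 9.38 and 5.07 sites per 1000 in replicates 1 and 2, against chromosome medians of 42.7 and 7.95.

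The symmetric CG motif was the motif type with the most tags in both libraries. It held 57.5% of nuclear tags and 31.4% of nuclear sites in replicate 2, and 41.8% and 17.7% in replicate 1. Of its covered sites, 94.7% in replicate 2 and 77.8% in replicate 1 were WGBS-methylated. Sites assigned to the single motif were WGBS-methylated in 70.3% of cases in replicate 2 and 36.8% in replicate 1. Of the other 7 motif types, 6 lay below the single motif in replicate 2, from 32.9% to 66.1%, and the motif symmetric around CNG lay above it at 87.4%.

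Genes for non-coding RNA carried 67.9 CG sites per 1000 CNNR cytosines in replicate 1 and 30.7 in replicate 2, close to the flanks of protein-coding genes in both libraries. In CHG they carried 52.9 and 15.6 per 1000.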
